A study of Schizosaccharomyces pombe with 20 samples.

How the data were processed

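Chromosome contacts were measured by in situ Hi-C, which joins and sequences DNA ends that lie close together in the nucleus, in 17 libraries of the fission yeast Schizosaccharomyces pombe, and RNA was sequenced in 3 libraries. The Hi-C libraries comprised 11 of a cdc25-22 strain at 8 times after a shift from 36C to 26C, and 6 of wild-type or mutant strains. Groups, temperatures and times were taken from the labels. Of the 8 times, 3 (60, 80 and 120 min) carried a second replicate, and every other group had 1 library. Labels of 10 of the Hi-C samples name a pair of libraries behind 1 map, so such a map was treated as 1 replicate. The labels do not say whether the second replicates came from separate cultures, so the spread between replicates may be technical. The p-values of single bins rest on that spread. Permutation p-values against time do not use it and treat all libraries as exchangeable. Libraries of the same or neighbouring times can be alike, so these p-values may overstate the evidence. All p-values describe these libraries only.

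The Hi-C values are deposited as symmetric matrices of contact signal in bins of 5, 10 and 20 kb. Per the labels, the genome build was ASM294v2. The aligner, the read filters and the balancing tool are not given in the sources used here. From the deposited signal values, row sums within a map differed by a coefficient of variation of at most 1.74%, so the authors had balanced each map. Totals differed between maps, and each map was therefore scaled to its own total. In each of the 17 maps 2441 of 2515 bins of 5 kb, 1222 of 1258 bins of 10 kb and 612 of 629 bins of 20 kb held values, but not always the same bins. Comparisons used the 2432, 1218 and 610 bins with values in every map. The number of bins of each chromosome matched the length in the reference annotation used here, a later release of the same assembly with equal chromosome lengths, from which gene positions were taken. Coordinates are 1-based.

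The RNA values are deposited as whole-number read counts per gene, made with STAR 2.5.2 and HTSeq 0.6.1 on ASM294v2, per the submitters' processing notes, which also name edgeR without its role. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as the Tf2 retrotransposons and the subtelomeric helicase genes, are uncertain. Of 6987 genes, 6840 identifiers matched the annotation and 147 did not.

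The mid-to-short ratio is the log2 of the mean contact per bin pair at 80 to 800 kb over that at 20 to 70 kb within chromosome arms (10 kb maps). Borders are local minima of an insulation profile, which averages contacts across a bin in a sliding window, with a minimum depth of 0.2 on the log2 scale. Small domains used a 40 kb window on 5 kb maps with 66 borders called in the wild type at 26C, and large domains a 200 kb window on 20 kb maps with 10 borders called at 20 min. Borders are picked for depth in the calling map, which was left out of the test against time. Centromere clustering is the log2 of the mean contact between bins within 100 kb of centromeres of different chromosomes over the mean of all contacts between chromosomes, and telomere clustering is the same for the terminal 100 kb of chromosomes I and II. The share of contacts between chromosomes was taken over all pairs at least 20 kb apart. Pearson's r and Spearman's rho against time were tested with 2-sided permutation tests of 100000 resamples, or exactly over all orders where fewer than 10 libraries entered. Benjamini-Hochberg adjustment covered the 6 measures. Per 20 kb bin, the mid-to-short log2 ratio was tested with limma 3.58.1 (trended variance, 8 times as groups, adjusted p under 0.05). Data were simulated with the spread left after the median difference between replicates was removed, an SD of 0.0377 per bin. On these limma recovered 60 of 60 bins changed by 0.25 in the comparison of 80 with 120 min, and called 2 unchanged bins among 610. That simulation had no shift shared by all bins of a library, so its recovery does not hold for the test without subtraction of the median bin. Genotypes had 1 library each and were set against the SD between replicates pooled over the 3 replicated times, without a test.

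RNA counts were scaled with TMM (edgeR 4.0.16), with DESeq2 1.42.0 size factors and total counts as alternatives. No gene was tested: fold changes carry exact 95% intervals from the conditional binomial distribution, which cover counting error only, since reads without molecular identifiers are not independent molecules. Genes with at least 20 counts in both libraries together entered, log2 folds had a prior count of 0.5, and a named gene at 0 is given with its interval only. Called genes had a fold over 2 and an interval that excluded 1. In simulated libraries with the depth of the cut3 comparison, 50 of 50 genes changed 2.5-fold were called, and 9 of 6787 unchanged genes. The changed genes were drawn only from protein-coding genes with counts far above the filter. Recovery near the limit of 20 counts was therefore not simulated. The unchanged genes include those below the count filter, which could not be called, as 5171 genes in all passed it. The 19 gene lists were fixed beforehand, and the median log2 fold of each was placed among 10000 random lists of equal size matched on expression. Of the 19 lists, 1 is not reported here. The others were condensin, cohesin, mitotic and cytokinesis genes, MBF (G1/S) genes, core histones, heat shock and chaperones, core stress response, ribosomal proteins, Tf2 retrotransposons, meiotic genes, mating genes, kinetochore and checkpoint, securin, separase and APC, heterochromatin and subtelomere, iron and phosphate starvation, DNA damage and topoisomerases, subtelomeric genes, and pericentromeric genes. Both RNA comparisons share 1 wild-type library, so unchanged libraries were simulated 100 times from Poisson counts.

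Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest log2 folds among protein-coding genes with at least 100 counts in the higher library and an interval excluding 1, the mutated genes, and the 4 largest absolute folds of each list. Named bins were the 5 largest rises and 5 largest falls past the threshold, at least 100 kb apart, and named borders the 5 strongest large-domain borders. Alternatives were renewed balancing, leaving out the bins in the lowest 5% of row sums of any map (in balanced maps these differ little), other distance classes, windows, bin sizes and border sets, leaving out each replicate, a replicate block, and other scalings, filters and prior counts for RNA. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.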

Results

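The study followed the folding of fission yeast chromosomes through the cell cycle and asked what the condensin and cohesin complexes contribute to it. The time course used a cdc25-22 strain, in which a temperature-sensitive form of the Cdc25 phosphatase stops cells before mitosis at 36C and lets them enter it together after return to 26C. Maps were made 20, 30, 40, 50, 60, 70, 80 and 120 min after the return, with 2 libraries at 60, 80 and 120 min and 1 at each other time. The 6 further maps came from wild type at 26C, wild type at 36C, the condensin mutants cut14-208 and cut3-477, the cohesin mutant rad21-K1 and a cut3-477 rad21-K1 double mutant. For Hi-C the mutants and the wild type at 36C were held there for 2 h, except cut14-208 with 1 h. Map totals on the 10 kb maps in units of 1e6 ranged from 25.41 to 29.06 in the main time series, from 7.7 to 11.52 in the second replicates and from 19.35 to 86.1 in the other maps. RNA was counted in wild type (22967137 counts), cut3-477 (22233710 counts) and cut14-208 (20357887 counts), with 1 library each after 2 h at 36C.

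Contacts between loci 80 to 800 kb apart first gained on contacts between near neighbours and then lost ground. The log2 mid-to-short ratio was -3.90 at 20 min, -3.08 at 30 min and -2.66 at 40 min, its highest value. It was -2.77 at 50 min, -3.24 ± 0.04 (SD, n = 2) at 60 min, -3.91 at 70 min, -4.26 ± 0.08 (SD, n = 2) at 80 min and -4.52 ± 0.13 (SD, n = 2) at 120 min. The course from 20 to 40 min spanned many times the pooled replicate SD of 0.0885. Against time the ratio fell over the 11 libraries, with r = -0.73 (permutation p = 0.0117, adjusted 0.0175) and rho = -0.828 (permutation p = 0.00273, adjusted 0.00546). Without the libraries at 120 min, the 2 farthest from the median time, r was -0.516 (exact permutation p = 0.155), so the linear relation rests on them. In the 8 libraries of the main series rho was -0.69 (exact permutation p = 0.0694). The second replicates, 3 libraries, were too few for a value of their own.

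**Figure D1:**
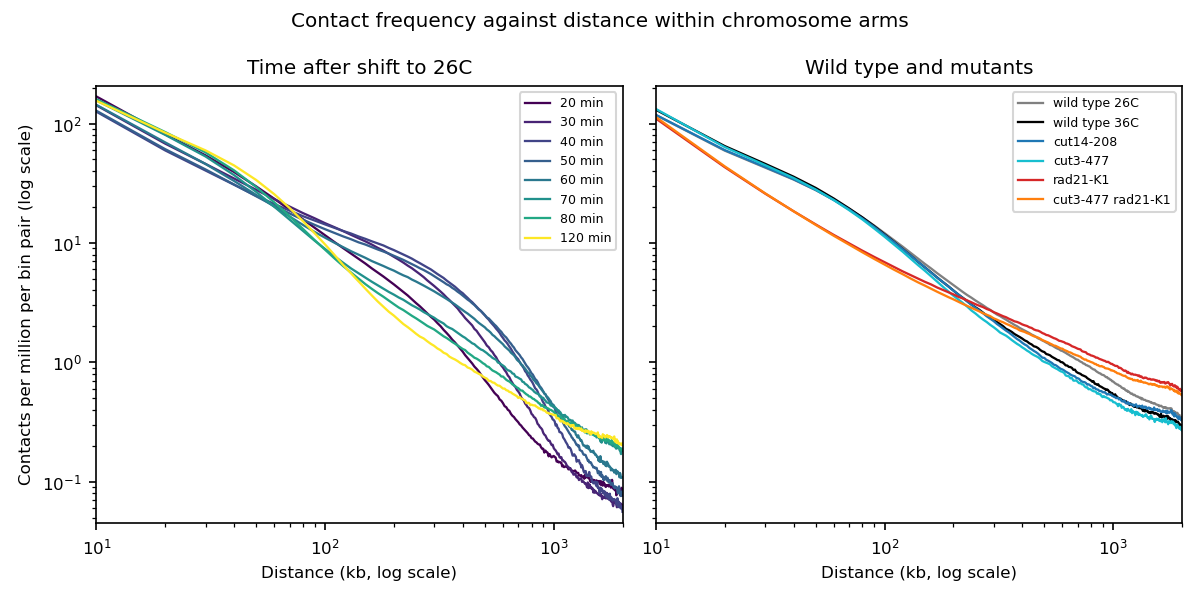
Contacts per bin pair, scaled to the map total, against distance in kb, both on log scales, within chromosome arms; 1 line per map, first replicates at left and wild type and mutants at right. Lines at 40 and 50 min bulge in the range of 80 to 800 kb (mid-to-short ratio -2.66 and -2.77), and the rad21-K1 and double mutant lines fall more evenly than the others.

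Large-domain borders called early and late in the time course mostly lay in different places. At 20 min 10 borders were called, on average 1 per 1258 kb, and 10 in each map at 120 min. Only 3 of the 20 min borders lay within 1 bin of a border called at 120 min. How far calls in 2 replicate maps coincide is not given here, so this count has no baseline. Of the 10 borders, 7 and 9 had a strength above 0 in the first and second library at 120 min. Among the 20 min borders the strongest lay on chromosome I from 1540001 to 1560000, in a bin with ire1, the sensor of unfolded proteins, and had a strength of 0.53 at 20 min and 0.62 at 30 min but 0.17 and 0.24 in the first libraries at 60 and 120 min. The next, on chromosome I from 4880001 to 4900000, held gas1 and bgs3, genes of cell wall synthesis, and went from 0.53 at 20 min to 0.05 in the first library at 120 min. A border on chromosome I from 3340001 to 3360000, with the clathrin heavy chain gene chc1, was 0.39 at 20 min and 0.30 in the first library at 120 min. On chromosome II the border from 2120001 to 2140000, at the silent mating-type cassettes, moved the other way, from 0.39 to 0.63. The fifth, on chromosome I from 2800001 to 2820000, with the nuclear export receptor gene crm1, went from 0.37 to 0.19.

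Mean strength of the 10 borders called at 20 min was 0.37 at 30 min, 0.30 at 40 min, 0.24 at 50 min, 0.18 at 70 min and 0.17 ± 0.01 (SD, n = 2) at 80 min. Over the 10 libraries other than the one used for border calling, the strength of these borders fell with time, with r = -0.80 (permutation p = 0.0061, adjusted 0.0122) and rho = -0.905 (permutation p = 0.00083, adjusted 0.00498). Leaving out the libraries at 120 min gave r = -0.962 (exact permutation p = 0.0004). In the main series alone, 7 libraries, rho was -0.964 (exact permutation p = 0.00278). The direction depends on the map in which borders are called, as sets chosen after seeing the data showed. Borders called in either library at 120 min gained strength, with rho = 0.781 (permutation p = 0.0106 and 0.0105). The 4 borders called in the wild type at 26C gave rho = -0.183 (permutation p = 0.586). No general fading of large-domain borders follows from these values.

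Small-domain borders weakened and then recovered. Mean strength at the 66 borders was 0.39 at 20 min, 0.31 at 30 min, 0.26 at 40 min and 0.25 at 50 min, and then 0.27 ± 0.02 (SD, n = 2) at 60 min, 0.28 ± 0.02 (SD, n = 2) at 80 min and 0.37 ± 0.02 (SD, n = 2) at 120 min. The dip and the return both exceeded the pooled replicate SD of 0.0183. Such a course has no single trend, and against time r was 0.307 (permutation p = 0.359, adjusted 0.431) and rho 0.27 (permutation p = 0.418, adjusted 0.502). Without the libraries at 120 min r was -0.587 (exact permutation p = 0.086). In the main series rho was -0.048 (exact permutation p = 0.935). With an 80 kb window rho was 0.622 (permutation p = 0.0453).

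Contacts between centromeres of different chromosomes stood out most from other contacts between chromosomes at 40 min and least at 120 min. Their clustering, an enrichment over the mean contact between chromosomes, was 3.35 at 20 min, 3.51 at 30 min, 3.56 at 40 min, 3.40 at 50 min, 3.33 ± 0.04 (SD, n = 2) at 60 min and 3.20 ± 0.02 (SD, n = 2) at 120 min. The enrichment fell with time by r = -0.772 (permutation p = 0.0057, adjusted 0.0122) and rho = -0.654 (permutation p = 0.0326, adjusted 0.0489). Without the libraries at 120 min r was -0.47 (exact permutation p = 0.201), so the relation rests on them. In the main series rho was -0.405 (exact permutation p = 0.327). Leaving out either library at 120 min gave rho = -0.543 (permutation p = 0.109 and 0.111), and leaving out the second library at 80 min gave -0.604 (permutation p = 0.0696). Scaled to the map total instead, a choice made after seeing the data, centromere contacts went the other way, from a log2 of 2.14 at 40 min to 3.00 ± 0.13 (SD, n = 2) at 120 min, with rho = 0.851 (permutation p = 0.00164). The fall is therefore one of enrichment only.

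The enrichment of telomere contacts went down and came back. Clustering of the ends of chromosomes I and II was 5.65 at 20 min, 4.86 at 40 min, 4.24 at 70 min and 5.13 and 5.70 in the libraries at 120 min. No trend over the whole course was found, with r = 0.003 (permutation p = 0.993, adjusted 0.993) and rho = -0.055 (permutation p = 0.875, adjusted 0.875). Without the libraries at 120 min r was -0.80 (exact permutation p = 0.00902), so the absence of a trend rests on them. In the main series rho was -0.595 (exact permutation p = 0.132). The pooled replicate SD was 0.2995. Scaled to the map total, rho was 0.691 (permutation p = 0.0221).

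Contacts between different chromosomes were least frequent at 30 min, shortly before mid-range contacts peaked. Their share was 7.52% at 20 min, 5.45% at 30 min, 5.84% at 40 min, 7.28% at 50 min, 9.57% ± 0.07 (SD, n = 2) at 60 min and 14.1% at 70 min. It stayed at 14.01% ± 0.07 (SD, n = 2) at 80 min and 14.5% ± 0.84 (SD, n = 2) at 120 min. The share rose with time, with r = 0.861 (permutation p = 0.00041, adjusted 0.00246) and rho = 0.842 (permutation p = 0.00201, adjusted 0.00546). Without the libraries at 120 min r was 0.885 (exact permutation p = 0.00257), and in the main series rho was 0.833 (exact permutation p = 0.0154).

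**Figure D2:**
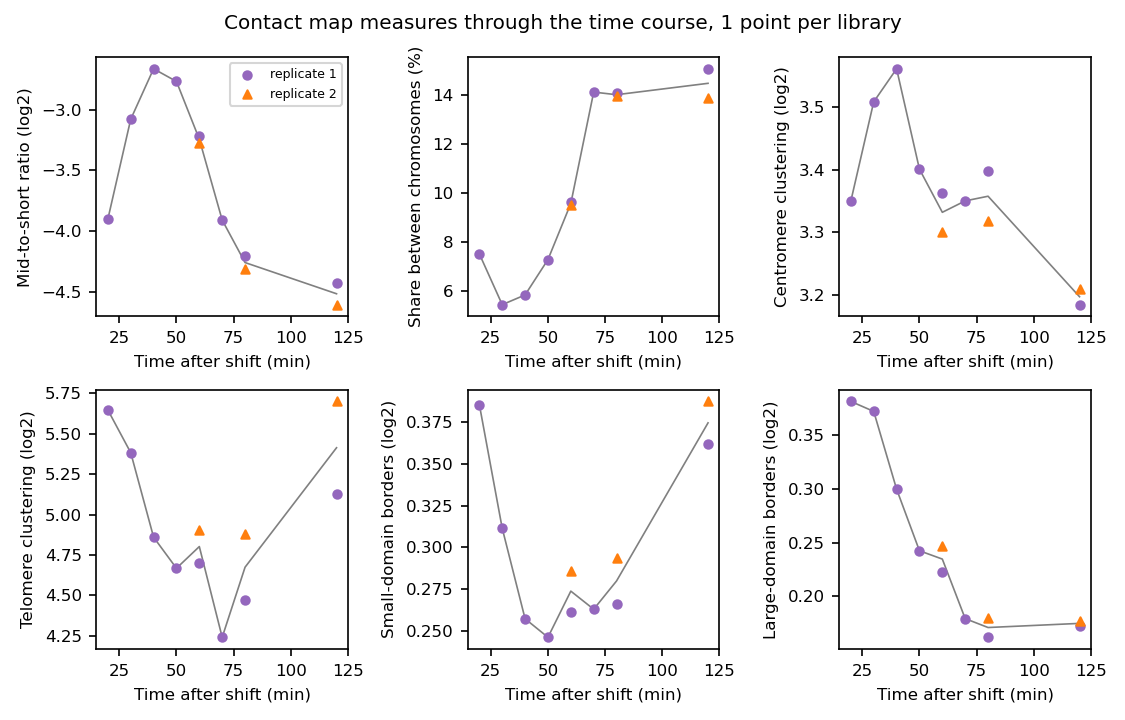
The 6 map measures against minutes after the shift, 1 point per library; circles are first and triangles second replicates, and the line joins the mean of each time. Mid-range contacts peak at 40 min (-2.66), while the share of contacts between chromosomes climbs from 5.45% at 30 min to 14.1% at 70 min.

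The loss of mid-range relative to near contacts by 120 min reached every measured part of the genome. Of 610 bins of 20 kb, 610 had a higher mid-to-short ratio at 20 to 40 min than at 120 min, with a median log2 difference of 1.24, and 610 had a higher ratio at 60 min than at 120 min, with a median of 1.16 (limma, adjusted p under 0.05). Near the centromere of chromosome I, the bin from 3780001 to 3800000 with rad50, a DNA repair gene, differed most at 20 to 40 min, by 1.96 ± 0.15 (SE, limma adjusted p = 1.3e-34). This p-value overstates the evidence, since bins of a library shift together and limma pools its spread over all 610 bins of only 11 libraries. The bin on chromosome II from 1580001 to 1600000, beside its centromere and with the RNA polymerase II gene rpb1, differed by 1.81. Next came chromosome II from 1700001 to 1720000 with the kinesin gene klp5 (1.73), chromosome III from 2380001 to 2400000 near an end (1.71), and chromosome III from 1040001 to 1060000 with the checkpoint kinase gene chk1 (1.69). At 60 min the largest differences were on chromosome III from 2380001 to 2400000 (1.82), chromosome II from 1680001 to 1700000 with pat1, the kinase that holds back meiosis (1.80), the same bin beside the centromere of chromosome I (1.71), chromosome III from 40001 to 60000 with the catalase gene ctt1 (1.68) and chromosome III from 1040001 to 1060000 (1.56).

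At 80 min against 120 min limma called 0 bins, while 81 of 610 had an unadjusted p under 0.05 and the median difference was 0.20, or 0.0796 to 0.32 when single libraries were left out. The first libraries had mid-to-short ratios of -4.21 at 80 min and -4.43 at 120 min, and the second -4.31 and -4.61. The count depended on the setting: on 10 kb maps 721 of 1216 bins were called, and leaving out the first library at 120 min gave 59. With the replicate number as a block 520 of 610 bins were called, all of them higher at 80 min. The 0 calls therefore do not show an absence of change.

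Because all bins moved together, each bin was also compared after subtraction of the median over all bins of its library, a choice made after seeing the data. Relative to that median 192 bins were higher and 152 lower at 20 to 40 min than at 120 min, 162 higher and 138 lower at 60 min, and 107 higher and 60 lower at 80 min. The 167 bins at 80 min became 92 (55 higher and 37 lower) without the first library at 80 min and 100 without the first library at 120 min. At 20 to 40 min the largest rise was again beside the centromere of chromosome I (0.72, limma adjusted p = 1.27e-06). The largest fall was on chromosome I from 5440001 to 5460000, near its right end, with klf1 (-0.48, limma adjusted p = 1.94e-07). Other falls lay on chromosome I from 1620001 to 1640000 with the nucleoporin gene nup184 (-0.39), from 4920001 to 4940000 with rvb1 (-0.33), from 4180001 to 4200000 with the kinetochore gene mal2 (-0.29) and from 1820001 to 1840000 with the uracil-regulated genes urg1 and urg2 (-0.27). At 80 min the largest fall was on chromosome I from 3960001 to 3980000 with the ubiquitin ligase gene pub1 (-0.27).

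The rad21-K1 map was flatter than the wild-type map at 36C. Maps of the condensin mutants stayed close to wild type in the measures of distance and small domains. No time after a release into mitosis is given for the mutant and wild-type maps, and their share of mitotic cells was not measured. Closeness to wild type here therefore does not speak to mitotic cells. In rad21-K1, a temperature-sensitive allele of the cohesin kleisin subunit, small-domain border strength was 0.11 against 0.30 in the wild type at 36C, -10.4 replicate SDs. Mid-to-short ratio in rad21-K1 was -2.93 against -3.62, higher by 0.70 or 7.88 replicate SDs. Contacts between chromosomes took 30.1% of the total against 17.1% (26.73 replicate SDs). Against that higher background its centromere enrichment was lower, at 2.89 against 3.29 (-9.36 replicate SDs), while centromere contacts scaled to the map total were higher, at a log2 of 3.91 against 3.45 (3.89 replicate SDs). No large-domain border was called in its map, against 5 in the wild type at 36C. One map stood for each genotype, so no difference between genotypes has a replicate check and none was tested. An effect of a mutation therefore cannot be told apart from a difference between libraries.

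The double mutant map lay near the rad21-K1 map in border strength and distance, but not in contacts between chromosomes. Small-domain border strength was 0.11, lower than in the wild type at 36C by -10.43 replicate SDs, and -0.03 replicate SDs from rad21-K1. Its mid-to-short ratio of -3.07 was above the wild type by 6.24 replicate SDs and below rad21-K1 by -1.63. Centromere clustering was 2.82, or -11.15 replicate SDs from the wild type at 36C, and 4.08 replicate SDs above it when scaled to the map total. Contacts between chromosomes took 32.5%, the highest share of the 17 maps and 5.02 replicate SDs above rad21-K1. The sample label gives this strain as cut3-477 rad21-K1, while the series design names a cut14 and cut3 double mutant.

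In cut14-208, a mutant of the condensin subunit Smc2, small-domain border strength was 0.26 (-2.17 replicate SDs from the wild type at 36C), and the mid-to-short ratio of -3.59 lay within 0.39 replicate SDs of it. The cut14-208 map came after 1 h at 36C and the wild-type map after 2 h. Genotype and time at 36C therefore cannot be told apart. Strength at the large-domain borders of the 20 min map was 0.10 in cut14-208 against 0.16 in that wild type (-4.45 replicate SDs). It was 0.14 in cut3-477, 0.06 in rad21-K1 and 0.05 in the double mutant. Contacts between chromosomes took 22.1% in cut14-208 against 17.1% (10.39 replicate SDs). In cut3-477, a mutant of the condensin subunit Smc4, small-domain border strength was 0.30 (-0.14 replicate SDs), the mid-to-short ratio -3.73 (-1.16 replicate SDs) and the share between chromosomes 19.6% (5.2 replicate SDs). Centromere clustering was lower than in the wild type at 36C in both, at 3.15 in cut14-208 (-3.46 replicate SDs) and 3.16 in cut3-477 (-3.09 replicate SDs), but not when scaled to the map total (2.29 and 0.34 replicate SDs). The wild-type maps themselves lay apart in some measures: the one at 36C had a mid-to-short ratio of -3.62 against -3.40 at 26C (-2.58 replicate SDs) and centromere clustering of 3.29 against 3.02 (6.47 replicate SDs), more in these measures than either condensin mutant lay from the wild type at 36C. They lay closer in the share between chromosomes (-0.95 replicate SDs). In large-domain strength, over all settings with borders called in neither wild type, a limit set after seeing the data, they lay -2.32 to -0.47 replicate SDs apart and cut14-208 lay -5.16 to -1.26 from the wild type at 36C. The ranges overlap, though in each setting cut14-208 lay farther than the wild types lay apart. With the bins of lowest row sum left out, cut14-208 differed from that wild type by -0.045 in centromere clustering instead of -0.148.

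**Figure D3:**
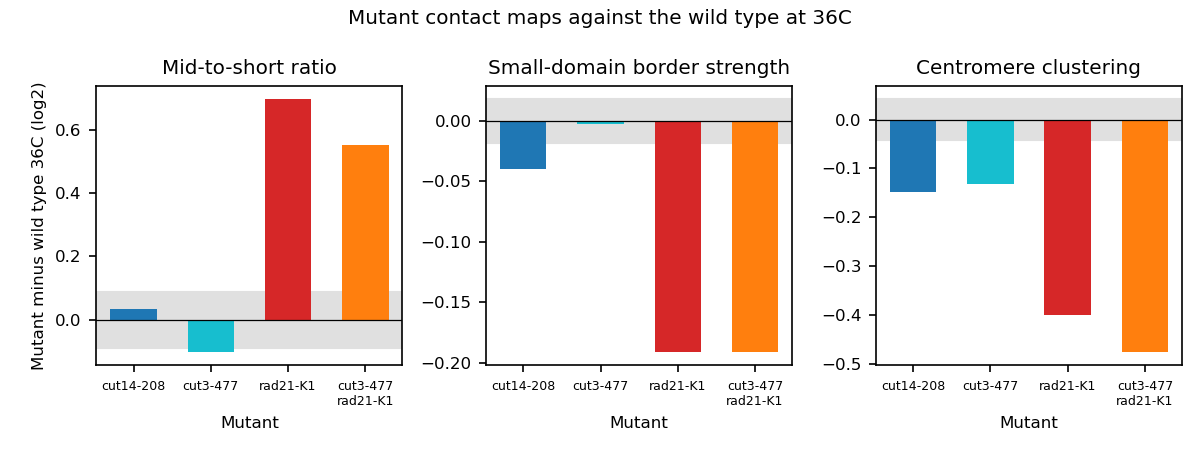
Difference of each mutant map from the wild type map at 36C, in log2 units, for the mid-to-short ratio, small-domain border strength and centromere clustering; 1 map per genotype, bars from 0, grey band of 1 pooled replicate SD either way. Both strains with rad21-K1 lie far outside the band in all 3 measures (rad21-K1 at 0.70, -0.19 and -0.40).

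In the cut3-477 RNA library 82 genes differed from wild type by over 2-fold beyond counting error, 13 higher and 69 lower. Of these, 6 and 51 were protein-coding, and with a minimum of 100 counts 39 genes were left. Galactose genes on the right arm of chromosome II stood at almost nothing. The galactokinase gene gal1 (4488298 to 4490271) had 0 counts against 875 (95% interval of the ratio 0 to 0.00446). For gal7 the counts were 0 against 444 (95% interval 0 to 0.00881). Beside them pan5, an enzyme of pantothenate synthesis, had 1 against 1972, a ratio of 0.000535 (95% interval 1.35e-05 to 0.00299). The same stretch lacked values in the cut3-477 contact map alone of the 17 maps (4 bins of 5 kb). The uracil synthesis gene ura4 on chromosome III (115589 to 116625), often used as a strain marker, was 585-fold lower, with 6 counts against 3703. Away from these, SPAC11D3.01c was 15.7-fold lower, the melibiase gene mel1 7.52-fold, pcm2 5.68-fold, SPBC1289.14 5.62-fold, lsd90 4.85-fold and prl65 4.39-fold. Higher genes moved less: the amino acid transporter gene agp3 was 2.03-fold, SPAC1039.02 and the iron oxidase gene fio1 1.99-fold, new25 1.84-fold, the iron permease gene fip1 1.82-fold, the siderophore transporter gene str1 1.69-fold, aes1 1.68-fold, SPAC11D3.04c 1.66-fold, rdh54 1.59-fold and SPAC8E11.10 1.52-fold. RNA comparisons had 1 library per genotype and therefore no replicate check and no p-value.

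Among the lists, core stress response genes were lower in cut3-477, with a median log2 fold of -0.70 over 16 genes against a central range of -0.05 to 0.13 for random lists, and 9 of the 16 were over 1.5-fold lower. They included rds1 (3.11-fold lower), the metallothionein gene zym1 (2.48-fold), ctt1 (2.43-fold) and the stress protein gene hsp9 (2.19-fold). Heat shock and chaperone genes had a median of -0.002, just under the range from 0.01, with hsp16 1.65-fold and ssa1 1.29-fold lower. Mating genes had a median of -0.32 (range -0.29 to 0.10), with map1, a regulator of mating, 1.66-fold lower. Subtelomeric genes had a median of -0.53 over 91 genes (range -0.16 to 0.01), and 23 were over 2-fold lower. Without the genes in the stretch missing from the contact map the median was -0.42 over 86 genes. Iron and phosphate starvation genes were the list that lay higher, with a median of 0.25 (range -0.09 to 0.12), though 7 of 12 were above 0 and 5 below. In it str3, fio1 and fip1 were higher while the acid phosphatase gene pho1 was 2.11-fold lower.

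In the cut14-208 RNA library 231 genes differed by over 2-fold, 71 higher and 160 lower. Of these, 20 and 79 were protein-coding, and with a minimum of 100 counts 124 genes were left. The glucose transporter gene ght1 was 45.9-fold higher (95% interval 37.6 to 56.5), with 4051 counts against 100. Iron uptake genes followed: fip1 5.77-fold, str1 5.64-fold, fio1 5.08-fold and the iron reductase gene frp1 4.87-fold higher. The uracil-regulated genes urg2 and urg1 were 3.76-fold and 3.32-fold higher, the glucose transporter gene ght5 2.92-fold, agp3 2.22-fold and mei2, the switch of meiosis, 2.17-fold. The lowest were gdt1 near the right end of chromosome I (5540032 to 5541481; 66.7-fold lower, 5 counts against 377), SPBC1289.14 (22.3-fold), the amino acid permease gene nrg1 (10.5-fold), the sterol deacetylase gene say1 (5.65-fold), mel1 (5.43-fold), SPAC11D3.01c (5.13-fold), SPBPB2B2.06c (4.59-fold), lsd90 (3.62-fold), cmt2 (3.61-fold) and ctt1 (3.37-fold).

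Subtelomeric genes were lower as a group in cut14-208, with a median of -1.15 over 91 genes (random range -0.20 to 0.04) and 47 over 2-fold lower. Medians were -0.52 at the left and -1.26 at the right end of chromosome I, and -1.09 and -1.52 at the left and right ends of chromosome II. Core stress response genes had a median of -0.42 (range -0.12 to 0.17), with the trehalase gene ntp1 2.45-fold and the stress regulator gene atf1 2.0-fold lower. Lower by less were MBF genes, expressed at the start of S phase, with a median of -0.34 (range -0.13 to 0.18), and core histones, with a median of -0.23 (range -0.17 to 0.24). Examples were tos4 (1.62-fold lower), the cyclin gene cig2 (1.58-fold) and htb1 (1.43-fold), while hht2 was 1.27-fold higher. Ribosomal protein genes were higher, with a median of 0.26 over 107 genes (range 0.03 to 0.18), led by rpl15 (1.58-fold) and rpl502 (1.56-fold). Iron and phosphate starvation genes had a median of 0.31 (range -0.13 to 0.15), but the list was split, with 6 of 12 above 0 and 6 below. Of them 5 were over 2-fold higher, including str3 (9.87-fold, 61 counts against 7), and 2 were over 2-fold lower.

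The other lists reported lay within the central 95% of random lists. In cut3-477 the medians were -0.05 for condensin, -0.03 for cohesin, 0.01 for mitotic and cytokinesis genes, 0.05 for MBF genes, 0.003 for core histones, 0.11 for ribosomal proteins, 0.08 for Tf2 retrotransposons, -0.30 for meiotic genes, 0.003 for kinetochore and checkpoint genes, -0.003 for securin, separase and APC, -0.08 for heterochromatin and subtelomere, 0.01 for DNA damage and topoisomerases, and 0.01 for pericentromeric genes. In cut14-208 they were -0.09 for condensin, -0.01 for cohesin, -0.03 for mitotic and cytokinesis genes, -0.08 for heat shock and chaperones, -0.42 for Tf2 retrotransposons, -0.22 for meiotic genes, -0.07 for mating genes, 0.12 for kinetochore and checkpoint genes, -0.06 for securin, separase and APC, -0.12 for heterochromatin and subtelomere, -0.04 for DNA damage and topoisomerases, and -0.01 for pericentromeric genes. The mutated genes were still transcribed: cut3 was at 0.856-fold in cut3-477 and 0.78-fold in cut14-208, and cut14 at 1.03-fold and 1.11-fold. These are point mutants, so transcript level does not check the labels.

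**Figure D4:**
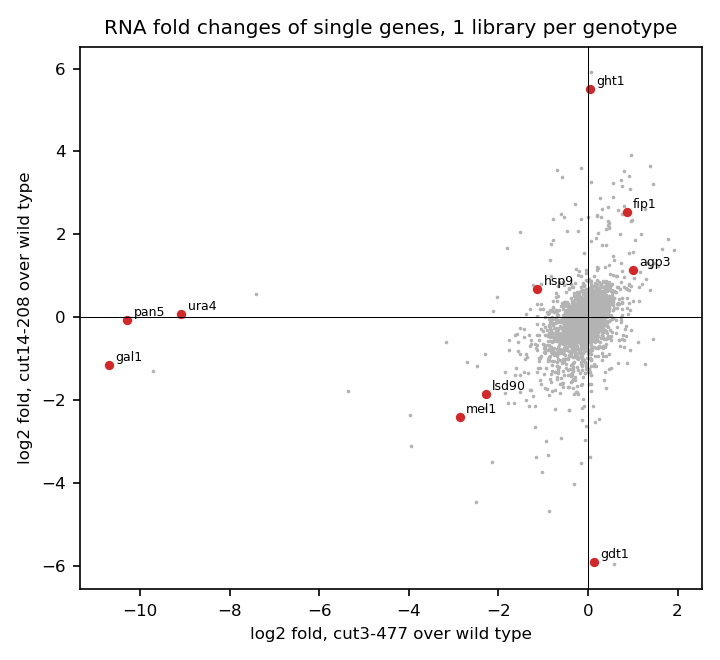
Log2 fold over wild type in cut14-208 against that in cut3-477, with a prior count of 0.5; 1 grey point per gene with at least 20 counts over the 3 libraries, and some named genes in red. The genes gal1, pan5 and ura4 are far lower in cut3-477 than in cut14-208, ght1 is higher (5.51) and gdt1 lower (-5.92) in cut14-208 and near 0 in cut3-477, and lsd90 and mel1 are lower in both.

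The mutants shared part of their lower genes. Of 69 lower genes in cut3-477 and 160 in cut14-208, 33 were in both, among them mel1, lsd90, ctt1, pho1 and SPBC1289.14, against 2.15 expected for independent lists and 0.37 in simulated unchanged libraries. The 33 also include gal1, gal7, gal10 and SPBPB2B2.08, from the stretch without values in the cut3-477 contact map. Of 11 and 55 higher genes, counted among those measured in both comparisons, 7 were in both, against 0.12 expected and 0.61 simulated. These were str3, agp3 and the non-coding SPNCRNA.1158, SPNCRNA.826, SPRRNA.05, SPRRNA.12 and snoR47. Across 5258 genes, which are not independent replicates, the folds correlated with r = 0.355, below the 0.475 that simulated unchanged libraries gave from the shared wild-type library alone. Their covariance was 0.0875 against 0.0183 in the simulation. Part of the overlap may come from the shared control, which is 1 library and could not be split.

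Core histone genes had lower insulation values than other genes on the 20 min map, but the call did not hold when neighbouring genes were counted once. Their median insulation value at 20 min was -0.177 over 10 genes against 0.004 for all genes, at the 0.2 percentile of 10000 random lists (2-sided permutation p = 0.0044, adjusted over 4 lists 0.0176). MBF genes had a median of -0.106 (permutation p = 0.0418, adjusted 0.0635) and mitotic and cytokinesis genes -0.039 (permutation p = 0.286, adjusted 0.286), so neither passed. With a 400 kb window, which left 5 of the histone genes, the histone value was -0.006 (permutation p = 0.991). With each 20 kb bin counted once, a choice made after seeing the data, 7 bins were left with a median of -0.175 (permutation p = 0.0186, adjusted 0.0587), so the list did not pass. On the 30 min map, with each gene counted, the histone median was -0.138 (permutation p = 0.0186, adjusted 0.0372).

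Genes at small-domain borders had a higher mean expression than other genes, but the difference did not pass the main test. The RNA came from wild type at 36C, while the borders of the main test were called in the wild-type map of the lower temperature. The mean log2 level in the wild-type RNA library was 9.94 over 136 genes in border bins and 9.53 over 4219 others, a difference of 0.40 (permutation p = 0.0673 over 10000 shifts of the border positions along the chromosomes). With borders called in an 80 kb window, 24 in number, the difference was 2.08 (permutation p = 0.0001, the smallest these shifts can give). With borders of the wild type at 36C, the temperature of the RNA, it was 0.55 (permutation p = 0.0163). The result of the main test therefore does not show an absence of a difference.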

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

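All tests of explanations in this part were chosen after the results were seen.

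The heat shock gene hsp9 was lower in cut3-477 (2.19-fold) and higher in cut14-208 (1.60-fold) against the same wild-type library, a log2 difference of 1.80 between the mutants. It drew attention as the 1 protein-coding gene with at least 100 counts in each mutant and wild-type pair that was over 1.5-fold lower in cut3-477 and over 1.5-fold higher in cut14-208, or the reverse, beyond counting error. The difference was not tested, since each mutant has 1 library.

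Genes around gal1 were almost without counts in the cut3-477 RNA library, while genes around gdt1 were almost without counts in the cut14-208 library. For the first stretch a candidate explanation is DNA missing from the strain: the 4 bins of 5 kb over the genes lacked values in the cut3-477 map and had values in the 16 other maps. An equally deep fall over the whole chromosome end is argued against by 10 neighbours within 40 kb, with a median log2 fold of -0.41. Their folds ran from -2.70 to 0.28, and most of them lie on the inner side of the stretch. Towards the end few genes had counts, and tlh2 there was the lowest (7 counts against 51). A milder fall of the chromosome end is not argued against. For the stretch around gdt1 missing DNA is argued against, since 5 of 5 bins over it held values in the cut14-208 map. It stays open why the double mutant, labelled with the same cut3-477 allele, has values in the gal1 stretch, and since every map lacks a fixed number of bins, a bin without values shows low coverage and not its absence.

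The double mutant map resembled the rad21-K1 map in border strength, though its share of contacts between chromosomes lay 5.02 replicate SDs higher. A strain without the rad21-K1 mutation, as the series design has it, stays open. Small-domain border strength lay -10.43 replicate SDs from the wild type at 36C, while neither condensin mutant alone went beyond -2.17. These values cannot decide, since no map of a strain known to carry both condensin mutations was available. The joint effect of both may exceed that of either alone. A strain with rad21-K1, as the sample label has it, remains a candidate explanation, with a difference of -0.03 replicate SDs from the rad21-K1 map.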

How the results depend on the processing

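The alternatives were fixed before the data were examined, except a border minimum of 0.1, subtraction of the median bin, large-domain borders called at 120 min or in the wild type at 26C, the count of each 20 kb bin once, and clustering scaled to the map total, which were chosen after seeing the data. Of 211 alternative values over 35 results, 153 kept their direction and call or stayed within the spread, and 7 reversed. All 22 values from renewed balancing kept their direction and call or stayed within the spread. So did 17 of 21 with the bins of lowest row sum left out. With those bins left out telomere clustering could not be computed, because all terminal bins go. For the others below, the cause was not tested unless named.

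Spearman's rho of the mid-to-short ratio against time was -0.69 in the 8 libraries of the main series, which are fewer. Centromere clustering gave -0.558 with regions of 60 kb, -0.60 without the bins of lowest row sum and -0.405 in the main series. It gave -0.732 to -0.543 when single replicates were left out. Scaled to the map total, centromere clustering reversed to 0.851 and telomere clustering gave 0.691, as this scaling does not divide by the mean contact between chromosomes. Small-domain strength gave 0.622 with an 80 kb window. Large-domain strength reversed to 0.781 and 0.781 with borders called in the first and second library at 120 min. It gave -0.183 with borders of the wild type at 26C. Whether picking borders for depth in 1 map or a change of borders with time underlies the reversal was not tested. Among bins, 10 kb maps gave 1216, 1216 and 721 calls at 20 to 40, 60 and 80 min against 120 min, of 1216 bins tested. Distances of 100 to 500 over 20 to 50 kb gave 3 calls at 80 min. Leaving out single replicates gave 0 to 59 calls at 80 min. Subtracting the median bin gave 344, 300 and 167 calls, and at 80 min this became 92 to 110 without single replicates among the compared times and at most 164 over all replicates left out.

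In the labels only the number ties replicates of different times together. Across bins, replicate differences nonetheless correlated at 0.404, 0.261 and 0.474 between times, and all second replicates were shallower. With 2 numbers only, a shared series or batch behind each number can be neither shown nor excluded. With the replicate number as a block, 520 bins were called at 80 min against 120 min instead of 0, and 263 after subtraction of the median bin. At 20 to 40 and 60 min the block left 610 and 610 bins called, and 403 and 370 after that subtraction.

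In 20 kb maps the mid-to-short difference from the wild type at 36C was 0.797 in rad21-K1 and 0.669 in the double mutant. Small-domain strength differed by -0.103 and -0.107 with an 80 kb window, -0.213 and -0.212 with borders of the wild type at 36C, and -0.156 and -0.153 with a minimum of 0.1. Centromere clustering differed by -0.333 and -0.415 with regions of 60 kb. Without the bins of lowest row sum it differed by -0.507 and -0.567, and in cut14-208 by -0.045. Scaled to the map total it reversed to 0.458 in rad21-K1, 0.48 in the double mutant, 0.27 in cut14-208 and 0.04 in cut3-477.

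For RNA, a minimum of 100 counts gave 39 genes in cut3-477 and 124 in cut14-208, from fewer genes measured, and a fold over 1.5 gave 236 and 469 by its looser limit. The correlation of folds was 0.328 with at least 100 counts and 0.391 with a prior count of 5. A 400 kb window left 0 of 4 lists past the threshold for insulation, with core histones at -0.006, counting each 20 kb bin once left 0, with core histones at -0.175, and the 30 min map gave 2. Expression at small-domain borders differed by 2.08 with an 80 kb window and 0.55 with borders of the wild type at 36C. Shallow maps limit single pairs most: up to 62.6% of 5 kb pairs held 0.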

Other observations

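The tests of explanations in this part, and the contacts described, were chosen after the data were seen. Contacts of telomeres with an inner part of chromosome II were enriched late in the time course. Values in this part are relative to the mean contact between chromosomes. From 2580001 to 2760000, a stretch that includes the heat shock gene hsp16 and the siderophore transporter gene str1, the mean log2 contact of 8 bins with the ends of chromosome I was -0.64 at 20 min, -0.41 at 30 min, -0.04 and -0.53 at 60 min, 0.56 and 0.55 at 80 min, and 1.31 and 1.26 at 120 min. A neighbouring stretch from 2920001 to 3040000, with the topoisomerase gene top1, went from -0.54 at 20 min to 1.69 and 0.78 at 120 min. Late rises were not particular to chromosome II. Telomere contacts of chromosome I from 4500001 to 4580000 went from -1.10 at 20 min to 0.76 and 0.45 at 120 min. Those of chromosome III from 1540001 to 1560000 went from -0.57 to 0.71 and 0.25. Of 598 bins, limma called 41 with higher telomere contact at 120 min than at 20 to 40 min and 3 lower, and 37 higher with the replicate number as a block.

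The mating-type locus met the centromeres of the other chromosomes most in the cohesin mutants. Its log2 contact with centromeres I and III was 2.66 in rad21-K1 and 2.90 in the double mutant against 0.67 in the wild type at 36C, with a replicate SD of 0.165. In the time course it went from 0.36 at 20 min to 1.29 at 50 min and to 0.17 and 0.03 at 120 min. At this locus the 10 kb bin from 2130001 to 2140000 lacked values at 40 and 50 min. Beside centromere III the 20 kb bin from 1060001 to 1080000 lacked values in rad21-K1 and the double mutant. Whether low coverage or shared reads affect these contacts was not tested. The ends of chromosome III met each other at 2.70 in rad21-K1 and 2.65 in the double mutant against 0.30 in the wild type at 36C, with a replicate SD of 0.083. Telomeres and centromeres were also less separate there, at -0.48 and -0.74 against -2.00.

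For the late telomere contacts of chromosome II, technical explanations were set against the values. Reads shared with the chromosome ends are argued against by the deepest map, wild type at 26C, at -0.83, and low depth by the shallow second map at 60 min, at -0.53. Cell cycle stage and time at 26C cannot be told apart, since each stage was sampled at 1 time only, with 1.26 in the second map at 120 min. A hypothesis left open is that the contacts may belong to the stage reached by 120 min.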
